A study of Homo sapiens with 6 samples.

How the data were processed

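MiRNA levels were measured in Hep3B, a human hepatocellular carcinoma cell line, after transfection with the empty expression plasmid pcDNA3.1 (Mock, 3 arrays) or the same plasmid carrying HDAC6 (HDAC6, 3 arrays). Groups and replicate numbers were taken from the sample titles. Per the labels, total RNA was isolated in 3 independent extractions per condition and mixed in equal amounts into a pool, and 10 ug was biotin-labelled for a GenoExplorer microRNA chip. The 3 arrays of a group may therefore be repeated hybridizations of 1 pool. Every p-value below measures the spread between arrays, which may be technical.

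Per the labels, the arrays were scanned on an Axon scanner and read with GenePix Pro 5.0. Spots judged poor by eye were removed, the mean signals of 3 spots per probe were averaged, and the values were quantile normalized and filtered by class in GenePlex 3.0. The background correction and the rule of the class filter were not given in the sources used here. The deposited values are on a log2 scale, which was read from the values themselves: they run from 3.52 to 15.8, and 79.7% of their antilogs are whole multiples of 1/18 within 0.02 of an eighteenth. Such steps arise when a mean over 6 arrays of 3 spots each is assigned by rank. The median per array lay between 7.51 and 7.58, so a change in the total amount of miRNA cannot be seen and every fold change is relative to the other probes of the array. No flag for detection or background was used, so the signal over background of single probes is unknown, and the number of arrays limits the precision.

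The table held 582 probe rows. The let-7f row was blank, which left 581 probes: 386 guide-strand, 83 star-strand (passenger), 104 precursor and 8 control probes. Probes ending in "-pre" were read as precursors and the others as mature miRNAs. Mature probes named without an asterisk were counted as guide strands, and those with an asterisk as star strands. Where both arms of a miRNA were named without an asterisk, both were counted as guide strands. Passenger arms may therefore be among the guide strands in every count and comparison below. The species prefix and leading zeros were dropped from the names, and older names such as miR-91 were kept. The probe sequences and a genome build were not used here, so no coordinates are given. Members of a family with near-identical sequences can bind each other's probes, and values within the let-7, miR-17, miR-29, miR-30, miR-181, miR-200 and miR-301 groups are uncertain to that extent. Binding of hairpins by mature probes, or of mature miRNA by precursor probes, could not be checked either. HDAC6 mRNA was not measured, so its level was not checked.

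HDAC6 arrays were compared with Mock arrays by limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited log2 values, two-sided, no covariate). P-values were adjusted by Benjamini-Hochberg over all 581 probes, control probes included, with a threshold of 0.05. The 21 miRNA lists covered families, genomic clusters, liver, liver cancer and hypoxia miRNAs, and markers of other cell types. Members were matched by name among guide strands counted in this way, so a list could hold both arms of a miRNA. The 17 lists with at least 3 measured probes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Differences between mature and precursor probes of the same miRNA were formed within each array and tested by limma over 77 pairs. Comparisons of 1 value per array used exact two-sided permutation tests, in which 3 arrays against 3 cannot give a p below 0.1.

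Groups, the tests of single probes and of lists, the lists and the alternatives were fixed before the data were examined, as was the rule for named miRNAs. For mature and precursor probes that plan held only counts and signs. The limma test over pairs and the permutation tests were not part of it. The rule took the 10 largest rises and the 10 largest falls among mature probes past the threshold whose groups did not overlap. It added 6 miRNAs by name (let-7i, miR-21, miR-122, miR-210, miR-221 and miR-222), up to 4 members per list with the smallest adjusted p, and the 5 mature probes with the highest mean. Other miRNAs named below were chosen after their values were seen.

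The alternatives were median centring of each array, repeated quantile normalization, the brighter probes alone, an intensity trend with robust priors, array weights, the replicate number as a block, mature probes alone, leaving out each array in turn, an adjusted p under 0.01, a treat test against a 1.2-fold change, and star strands added to the lists. Averaging probes of the same name moved nothing, because no name occurred more than once. The planned pseudocount applied only to linear values. An offset at the 25th percentile of the antilogs, centring on 7 small RNA control probes and removal of the 8 control probes were added after the data were seen.

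The limma step was tested on simulated values for the HDAC6 against Mock comparison with the real means and variances of the 581 probes. It called 13 of 67 probes changed by 0.5 on the log2 scale, 56 of 67 changed by 1, 66 of 66 changed by 2, and 4 of 381 left without a change. No called probe had the wrong sign.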

Results

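The study compared the miRNA profile of Hep3B cells, a human hepatocellular carcinoma line, that had received the empty plasmid pcDNA3.1 (Mock) with that of cells given the plasmid carrying HDAC6, a mainly cytoplasmic deacetylase that acts on tubulin. The question, per the series title, was which miRNAs HDAC6 regulates in hepatocellular carcinoma. There were 3 arrays per group, each with normalized log2 signals for 581 probes. Arrays of the same group correlated at r = 0.922 to 0.952 across probes in Mock and 0.937 to 0.959 in HDAC6, whereas arrays of different groups correlated at 0.779 to 0.848. The median SD of a probe over 3 arrays was 0.294 in Mock and 0.242 in HDAC6 on the log2 scale. RNA from 3 extractions was pooled per condition, so this spread may be technical.

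The largest rise was that of miR-302e, from 7.14 ± 0.12 in Mock to 10.44 ± 0.58 in HDAC6 on the log2 scale (mean ± SD, n = 3), which is 9.85-fold (limma, adjusted p = 0.0012). The probe for miR-574-5p rose 5.43-fold, from 9.96 ± 0.08 to 12.40 ± 0.20 (adjusted p = 0.0011). MiR-1827, miR-297 and miR-125a-3p rose 5.19-fold, 4.61-fold and 4.17-fold, with log2 fold changes of 2.38 (SE 0.296), 2.21 (SE 0.252) and 2.06 (SE 0.211). The next rises were those of miR-566, miR-1303, miR-571, miR-1285 and miR-1273, between 3.11-fold and 3.78-fold. Adjusted p-values of these 10 miRNAs lay between 0.0011 and 0.0029.

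Among the falls, miR-301b decreased from 9.70 ± 0.35 to 7.34 ± 0.35 (5.14-fold lower, limma, adjusted p = 0.0020) and its relative miR-301a fell by 1.83 on the log2 scale (SE 0.241, adjusted p = 0.0027). MiR-29b, whose family represses collagen genes, fell from 10.98 ± 0.24 to 9.05 ± 0.44 (3.80-fold lower, adjusted p = 0.0027). MiR-192, abundant in liver, fell from 13.15 ± 0.14 to 11.26 ± 0.91 (3.72-fold lower, adjusted p = 0.0095). MiR-30b, miR-342-3p, miR-186 and miR-429 were 3.67-fold, 3.41-fold, 3.40-fold and 3.39-fold lower, and miR-2116* was 4.62-fold lower. The star strand miR-335* fell by 2.42 (SE 0.616, adjusted p = 0.0155), a call that was lost without Mock 1 (adjusted p = 0.055), Mock 2 (0.05) or HDAC6 3 (0.0524).

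Across the array, 266 of 581 probes passed the test, 124 higher and 142 lower in HDAC6, and 168 of them differed at least 2-fold (70 higher and 98 lower). With control-probe centring 166 passed (81 higher and 85 lower), and with the offset 88 differed at least 2-fold (41 higher and 47 lower). Repeated quantile normalization gave 134 higher and 113 lower, so which side was larger depended on the scaling. The groups did not overlap for 56.8% of the probes, against 10% by chance for 3 independent samples against 3. These arrays may instead be repeated hybridizations of 1 pool per condition. The rule of the class filter is unknown, so whether it raised the share of changed probes cannot be told. Guide-strand probes made up 80 of the higher and 114 of the lower calls, and star strands 12 and 22. None of the 8 control probes passed (limma, 0 at an unadjusted p under 0.05 as well), although 1 did without Mock 2 or HDAC6 2. Star strands called lower numbered 10 without HDAC6 3, 12 without HDAC6 1, 14 without Mock 1 and 7 with arrays centred on control probes, where 53 guide strands were higher and 76 lower. Of the brightest mature probes, miR-19b fell by 1.38 (SE 0.262), and miR-1207-5p and miR-1268 rose 1.94-fold and 2.41-fold. MiR-1972 rose 1.89-fold (adjusted p = 0.0187, but 0.0655 without HDAC6 3). MiR-1978 held the top rank on all 6 arrays, where quantile normalization gives it the same value of 15.78, so that its change could not be measured.

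**Figure D1:**
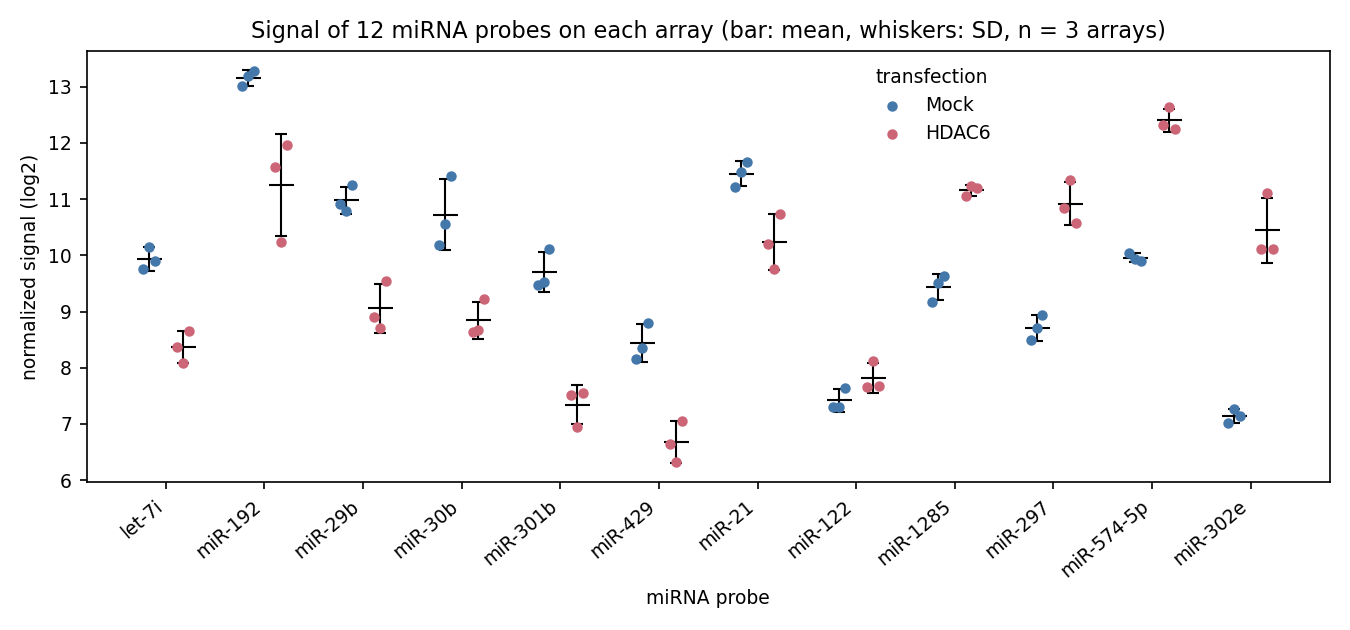
Normalized log2 signal (vertical axis) of 12 miRNA probes (horizontal axis) on each array, with Mock in blue, HDAC6 in red, a bar for the mean and whiskers for the SD of 3 arrays. The HDAC6 arrays lie below the Mock arrays for the first 7 probes, from let-7i to miR-21, and above them for the last 5; miR-122, with an adjusted p of 0.166, did not pass the test.

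Of the miRNAs fixed by name, let-7i, from a family that represses RAS and MYC, fell from 9.93 ± 0.21 to 8.37 ± 0.29 (2.95-fold lower, n = 3, limma, adjusted p = 0.0028). MiR-21, a widely studied oncogenic miRNA, fell by 1.22 on the log2 scale (SE 0.282, adjusted p = 0.0113). MiR-221 and miR-222, which repress the cell cycle inhibitor p27, fell by 0.84 (SE 0.282, adjusted p = 0.041) and by 1.05 (SE 0.332, adjusted p = 0.0326). Both passed in that pair's list adjusted over the list alone, but both calls were lost without Mock 1, Mock 3, HDAC6 1 or HDAC6 3, with adjusted p from 0.0789 to 0.128, and with arrays centred on control probes (0.109 and 0.068). They were also lost with the replicate number as a block (0.0783 and 0.0521). The hypoxia miRNA miR-210 had a log2 fold change of -0.68 (SE 0.268, adjusted p = 0.0697), and miR-122, the main hepatocyte miRNA, one of 0.40 (SE 0.219, adjusted p = 0.166). MiR-210 passed with array weights (0.0454), with the replicate block (0.0463) and without HDAC6 3 (0.0477).

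In the let-7 family, let-7i was the 1 of 8 measured probes that passed, both over all probes and adjusted over the list alone. The same count of 1 was found under each other scaling of the arrays, but 2 passed without Mock 1 or without Mock 2. In other fits let-7g also passed among brighter probes (adjusted p = 0.046) and with array weights (0.0499), and miR-98 with a trend and robust priors (0.0456). With the replicate number as a block, let-7g (0.0453) and miR-98 (0.0496) both passed. The other 7 had a mean log2 fold change of -0.49. Within each array, let-7i lay above the mean of those 7 by 0.516 ± 0.410 in Mock and at -0.561 ± 0.143 from it in HDAC6 (n = 3). The difference of -1.08 had an exact permutation p of 0.1, the smallest that 3 arrays against 3 allow. As a list, let-7 did not pass camera (adjusted p = 0.0887), and passed without Mock 1 (0.031).

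In several other families most members fell. All 5 measured members of the miR-30 family fell, with miR-30a at -1.62 (SE 0.261) and miR-30e at -1.58 (SE 0.249), and the list median was -1.58 (camera, adjusted p = 0.00779, and adjusted p = 0.332 with an estimated correlation). The miR-200 family, which maintains epithelial identity by repressing ZEB1 and ZEB2, fell in all 4 measured members, including miR-200a at -1.63 (SE 0.234) and miR-141 at -1.25 (SE 0.264), with a median of -1.47 (adjusted p = 0.0158, and adjusted p = 0.332 with an estimated correlation). All 3 miR-29 members fell, with a median of -1.66 (adjusted p = 0.0289, but 0.0617 without Mock 3, 0.0571 among mature probes alone, and adjusted p = 0.332 with an estimated correlation). With the offset the miR-29 median was -1.09. Adjusted over the list alone, the counts for these 3 families were the same. Of 12 measured members of the proliferation-linked miR-17/92 cluster and its paralogs, 10 fell, among them miR-25 at -1.37 (SE 0.258) and miR-20b at -1.33 (SE 0.257), and 12 did when adjusted over the list alone. Their median was -1.196 (adjusted p = 0.00118, and adjusted p = 0.332 with an estimated correlation), and 6 fell without HDAC6 1.

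Calls in other families were fewer. In the miR-181 family 3 of 4 fell, led by miR-181c at -1.74 (SE 0.246), with the miR-181b call (adjusted p = 0.0438) lost without any array but Mock 2 or HDAC6 2 (0.0789 to 0.159) and with control-probe centring (0.19). In the p53-induced miR-34 family miR-34a fell by 1.24 (SE 0.183) and miR-34b by 0.79 (SE 0.228), while miR-34c-3p was at 0.47 and did not pass (adjusted p = 0.0826). This list did not tell arms apart, so its members may not be the same arm of each miRNA. The other arm of miR-34b, miR-34b*, stood outside the list as a star strand and also fell, by 0.79 (SE 0.248, limma, adjusted p = 0.0323). MiR-34b lost its call under repeated quantile normalization (0.0729), where miR-34c-3p passed (0.0272), under control-probe centring (0.119) and without Mock 1, HDAC6 1, HDAC6 2 or HDAC6 3 (0.0527 to 0.0842). In the miR-15/16 family, miR-195 fell by 1.57 (SE 0.356) and miR-503 by 0.71 (SE 0.181) of 6 measured, and the miR-503 call was lost under repeated quantile normalization (0.186), control-probe centring (0.174), with the offset, at -0.28 (0.0549), and without Mock 1, HDAC6 1 or HDAC6 3. Adjusted over the list alone, 3 miR-181 members and 4 miR-15/16 members were lower, and in miR-34 2 were lower and 1 higher. None of the 3 lists passed camera (adjusted p = 0.0688 for miR-181, 0.413 for miR-34 and 0.0887 for miR-15/16). The miR-34 list median of -0.79 was -0.40 with the offset. MiR-181 passed under repeated quantile normalization (0.0379) and without Mock 2 (0.0408).

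Of 11 probes in the list called hepatocyte-enriched, 8 fell, including miR-148a at -1.66 (SE 0.230), miR-101 at -1.66 (SE 0.264) and miR-22 at -1.08 (SE 0.208), while miR-885-3p rose by 1.43 (SE 0.227) and miR-122 and miR-885-5p did not pass. The falls also included miR-21, miR-103 and miR-107, which stand in the carcinoma-raised or hypoxia lists too. The list median was -1.08, against -0.87 for all 183 guide strands numbered under 500, a class set after the values were seen. Among 15 probes of miRNAs known to be raised in hepatocellular carcinoma, the median was -1.10, and 15 were lower when adjusted over the list alone. Over all probes 13 fell and 0 rose, for example miR-96 at -1.12 (SE 0.226) and miR-301a at -1.83 (SE 0.241). Without HDAC6 1 this count was 7, without Mock 1 it was 8, and with arrays centred on control probes it was 8. Among 7 hypoxia-induced miRNAs, with a median of -1.03, 6 fell, such as miR-23a at -1.06 (SE 0.234) and miR-26b at -1.35 (SE 0.311), and 7 when adjusted over the list alone. With control-probe centring 3 fell, and miR-23a and miR-24 lost their calls (0.0572 and 0.0656). The camera adjusted p was 0.0289 for the hepatocyte, 0.00037 for the carcinoma and 0.0158 for the hypoxia list, and all 3 calls were lost with an estimated correlation (adjusted p = 0.332 with an estimated correlation). The hepatocyte call was also lost without Mock 3 (0.0682) and among mature probes alone (0.0685), and its counts adjusted over the list alone were the same.

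MiRNAs known to be lowered in hepatocellular carcinoma moved both ways. MiR-125a-3p rose by 2.06, miR-139-3p by 1.25 and miR-214 by 1.24 (SE 0.211, 0.1998 and 0.208 in that order), while 7 of the 16 measured probes fell, including miR-29b, miR-29c and miR-101. The list did not tell arms apart: miR-125a-5p, the other arm of miR-125a-3p, was at -1.80 (SE 0.656) and did not pass (adjusted p = 0.0558). Adjusted over the list alone, 3 were higher and 8 lower, and the list did not pass camera (adjusted p = 0.193). The imprinted 14q32 cluster, with 11 measured probes, had 4 higher and 2 lower, both over all probes and adjusted over the list alone: miR-127-3p rose by 1.47 (SE 0.204), miR-323-5p by 0.93 (SE 0.206) and miR-493 by 0.90 (SE 0.235), and miR-494 fell by 1.07 (SE 0.223). The 2 lower became 1 without Mock 1, Mock 3, HDAC6 1 or HDAC6 3, with repeated quantile normalization, with control-probe centring and with the offset. The list median was 0.47 (camera, adjusted p = 0.175) and 0.30 without HDAC6 3, and 2 were higher without HDAC6 1 and with control-probe centring. MiR-493 lost its call in both, and without Mock 1 or HDAC6 3 (adjusted p from 0.0527 to 0.0607). In the placental C19MC cluster miR-524-5p fell by 1.40 (SE 0.241), the 1 of 3 members to pass over all probes and over the list alone (camera, adjusted p = 0.199). MiR-371-5p and miR-373, which share a cluster, did not pass, at -0.28 (adjusted p = 0.286) and -0.13 (adjusted p = 0.656), and the sign of miR-373 turned with repeated quantile normalization.

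Markers of other cell types were few on the array. Of 4 haematopoietic probes, miR-146a fell by 1.53 (SE 0.267) and miR-486-3p rose by 0.89 (SE 0.207, a call lost with control-probe centring at an adjusted p of 0.0572). Their median was 0.14, their mean -0.09 and camera's direction up (adjusted p = 0.784). Of 4 fibroblast and smooth muscle probes, 3 of which stood in another list, miR-214 rose, and the median was -0.02, the mean 0.14 and camera's direction up (adjusted p = 0.784). Among 5 neural probes miR-128a fell by 1.53 (SE 0.243), miR-153 by 0.59 (SE 0.198), and miR-219-2-3p rose by 0.70 (SE 0.203), with camera at an adjusted p of 0.575 and directional fry, lower, at 0.0191. The miR-153 call was lost without any array but Mock 2 (adjusted p from 0.0775 to 0.129) and the miR-219-2-3p call without Mock 1, HDAC6 1 or HDAC6 2 (0.063 to 0.0919), and both were lost with control-probe centring. MiR-153 also lost its call with repeated quantile normalization, at -0.34 (0.173), and with the offset, at -0.27 (0.0834). Adjusted over the list alone, these counts were the same. Endothelial and striated muscle markers had 0 probes among guide strands.

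In all, 7 of 17 tested lists were lower and 0 higher by camera, with 8 lower and 0 higher at an unadjusted p under 0.05. With an estimated correlation 0 passed, and 0 did at an unadjusted p under 0.05. By fry, which asks whether the members of a list move on balance in 1 direction, 14 were lower and 1, the 14q32 cluster, was higher. The lists overlap: 8 of 15 carcinoma-raised probes, 5 of 11 hepatocyte probes, 4 of 12 miR-17/92 probes and 3 of 7 hypoxia probes also stood in another list. Camera set each list against all other probes, including precursors (median 0.18) and guide strands numbered from 500 (median 0.33). Apart from miR-500 and the miR-885 arms, members of the 7 lower lists are guide strands numbered under 500. Of those 183, 97 fell and 13 rose (median -0.87). That class was set after the values were seen, and no list was tested against it.

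**Figure D2:**
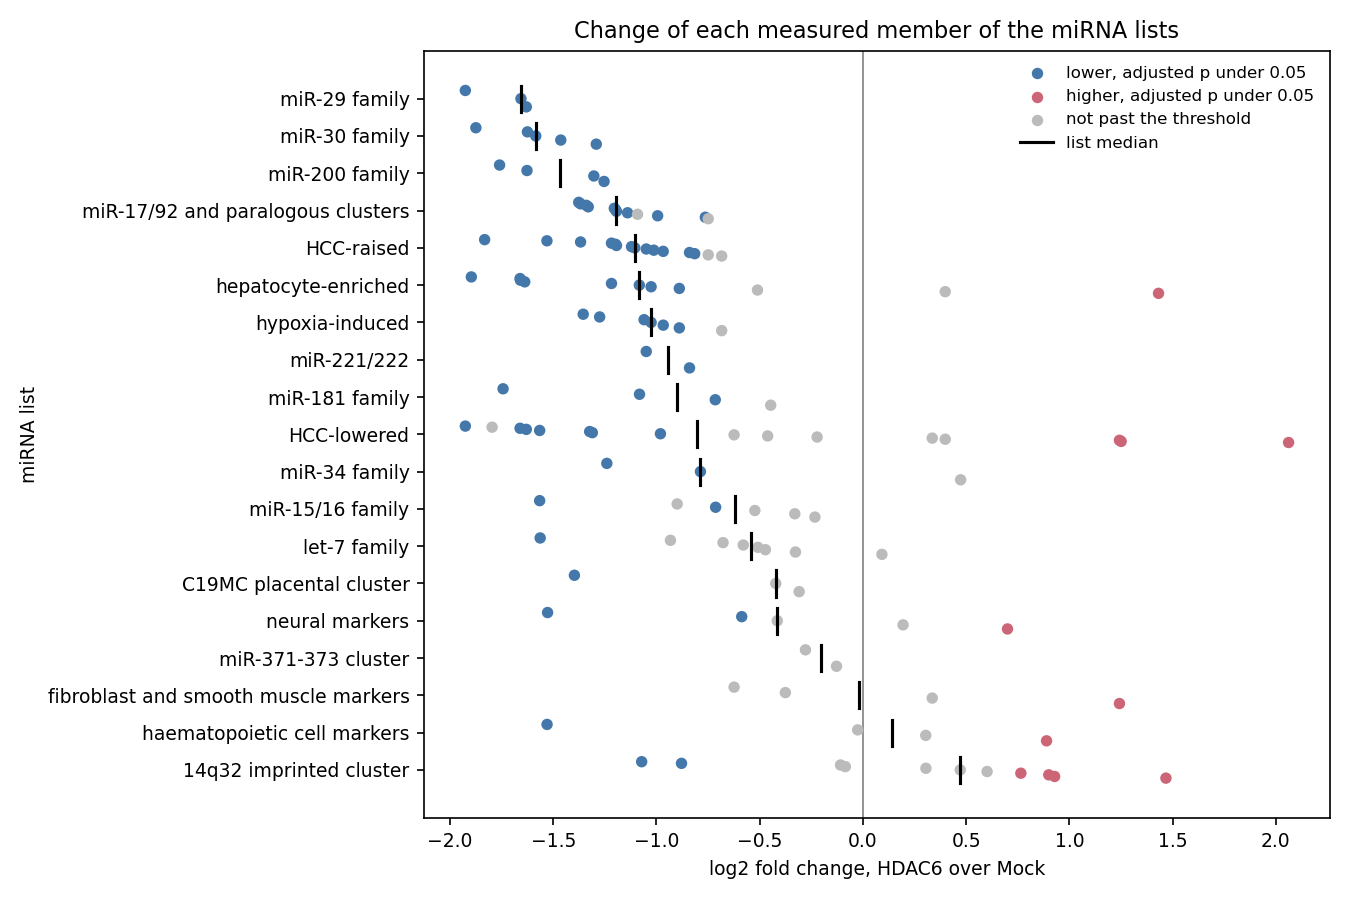
Log2 fold change of HDAC6 over Mock (horizontal axis) for each measured guide-strand probe of the miRNA lists (vertical axis), coloured by its call at an adjusted p under 0.05, with a black line at the list median. The miR-29, miR-30 and miR-200 members all lie below 0, and the 14q32 median lies at 0.47.

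Precursor probes, named for the hairpin from which a miRNA is cut, went up more often than down: 32 of 104 rose and 6 fell. Of 386 guide-strand probes 80 rose and 114 fell. Binding of either form by the other's probe could not be checked, so these may not be separate measures of hairpin and mature miRNA. The 6 falls became 1 without Mock 1 or HDAC6 3, 2 with repeated quantile normalization, 3 with the offset, and 2 with control-probe centring, where 18 rose. The clearest opposite pair was miR-192, whose mature probe fell by 1.90 while its precursor rose by 1.69 (SE 0.389), a difference of -3.59 (SE 0.643, limma over pairs, adjusted p = 0.0133). The miR-125a-5p probe differed from its precursor by -3.04 (SE 0.621) and the miR-30c probe by -1.62 (SE 0.317), both at an adjusted p of 0.0133. On its own miR-125a-5p did not pass (limma, adjusted p = 0.0558). The other arm, miR-125a-3p, was higher relative to the same precursor, by 0.81 (SE 0.277, adjusted p = 0.0434). For let-7i the difference was -1.25 (SE 0.356, adjusted p = 0.0245), a call lost without Mock 3 (0.0652), HDAC6 1 (0.108) or HDAC6 2 (0.0693). In contrast, miR-574-5p and its precursor rose together, by 2.44 and 2.34.

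Over 77 pairs of mature and precursor probes, the mature probe was lower relative to its precursor in 24 and higher in 9, and 44 did not pass. The pairs were not all independent, because both arms of some miRNAs were set against the same precursor probe. Both miR-339 arms are among the 24, and miR-125a stands there by its 5p arm and among the 9 by its 3p arm. Copy numbers were dropped in pairing, so miR-30c was set against the miR-30c-1 precursor. The median difference was -0.40. By number, a split chosen after the values were seen and with no test of the difference between the classes, it was -0.92 in the 48 pairs under 500 (21 mature lower and 2 higher) and 0.05 in the 29 pairs from 500 (3 lower and 7 higher). Of 11 pairs in which both probes passed on their own, 10 moved the same way, and miR-192 was the exception. The count of 24 was 8 without HDAC6 1, 15 without Mock 1 and 15 without HDAC6 2. Within arrays, the median of the guide strands exceeded that of the precursors by 0.936 ± 0.163 in Mock and 0.683 ± 0.029 in HDAC6 (n = 3), a difference of -0.25 with an exact permutation p of 0.1, the smallest possible.

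**Figure D3:**
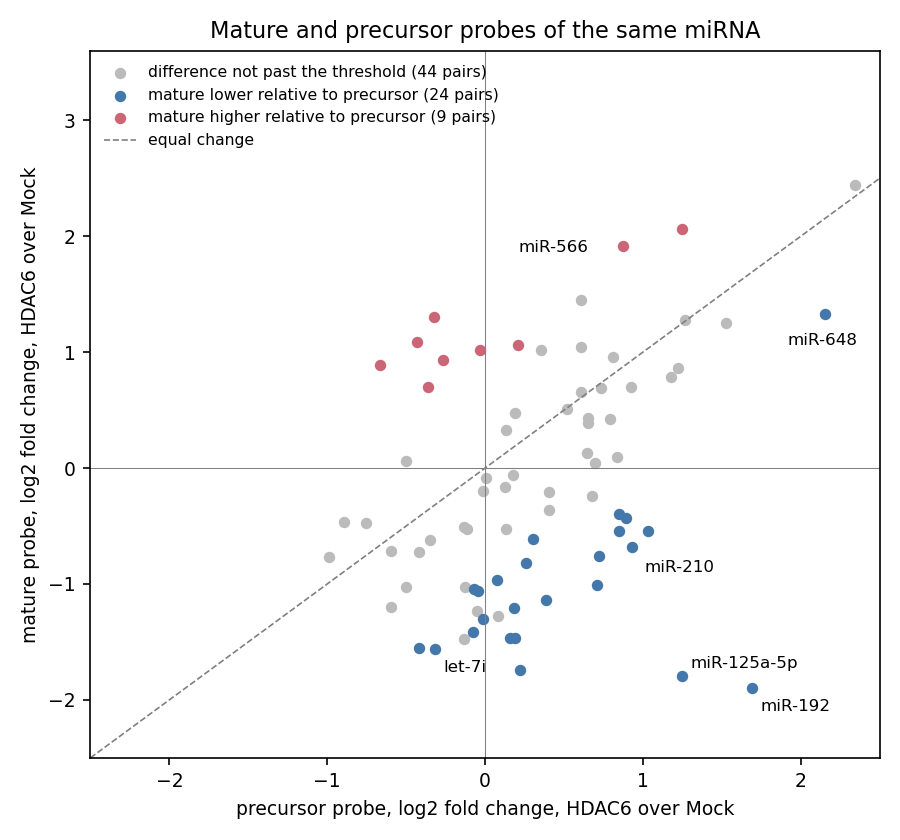
Log2 fold change of HDAC6 over Mock for the mature probe (vertical axis) against that of the precursor probe (horizontal axis) of the same miRNA, for 77 pairs, with a dashed line at equal change and colours for pairs whose difference passed the test. Points below the line, such as miR-192, have a mature probe that is lower relative to its precursor, as in 24 blue pairs against 9 red ones.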

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

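Removing the 8 control probes, centring on 7 small RNA control probes and the offset were chosen after the data were seen. The count of 266 changed probes was 271 with median centring, 247 with repeated quantile normalization, 282 with a trend and robust priors, 336 with array weights and 268 without the control probes. Which side was larger depended on the setting. The main fit gave 124 higher and 142 lower, repeated quantile normalization 134 and 113, and the offset 120 and 118. Repeated quantile normalization shifted the median log2 fold change of all probes from -0.09 to 0.08. Leaving out each array in turn gave 179 to 249 changed probes, 93 to 139 lower ones and 8 to 22 pairs with the mature probe lower, with 1 array fewer to test on. Among the 290 brighter probes alone 173 changed, 93 higher and 80 lower, 63 were lower at least 2-fold, and the median correlation within groups was 0.904. In that setting 4 pairs had the mature probe lower, a count not out of all 77, because only pairs with both probes among the brighter ones entered. With control-probe centring, 166 changed (81 higher and 85 lower). With the offset, which shrinks the changes of dim probes by construction, 88 differed at least 2-fold (41 higher and 47 lower). An adjusted p under 0.01 left 130. Lists past the threshold numbered 0 with an estimated correlation, 15 by directional fry and 17 by mixed fry, which answers another question than camera. Among named miRNAs and lists, signs turned only for values that did not pass: miR-373 (0.0778), miR-525-3p (0.00144) and the haematopoietic list (median 0.16, direction down) with repeated quantile normalization, that list among brighter probes (median -0.0255), and miR-150 with control-probe centring (0.0576). The fibroblast list median turned from -0.02 to 0.11 with repeated quantile normalization, and to 0.06 both with control-probe centring and with the offset. Without single arrays, miR-150 ranged from -0.47 to 0.26, miR-145 from -0.47 to 0.79, the fibroblast list median from -0.40 to 0.30 and the haematopoietic list median from -0.05 to 0.27. Of 87 named miRNAs, 76 kept their side of the threshold with control-probe centring and 11 lost their call, and with repeated quantile normalization 83 kept it, 3 lost their call and 1 gained one. The causes of these differences were not tested. Same-numbered arrays did not deviate together (r = 0.160, -0.0865 and 0.192), so the numbers were not taken as pairs. With the replicate block, 264 probes changed, 246 of them shared with the 266, 4 named miRNAs gained a call and 4 lost one, and not every array correlated best with its own number. Signal over background is unknown, which limits what can be said of dim probes.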

Other observations

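The tests of arm pairs, the counts of Alu-derived miRNAs, the split of precursor pairs by number and the test of a lower share of short RNA on high-numbered guide strands were chosen after the values were seen. Of 92 miRNAs with both arms measured, 25 had both arms past the threshold, and of these 22 moved the same way and 3 moved apart. MiR-195 fell by 1.57 (SE 0.356) while miR-195* rose by 1.51 (SE 0.185), a difference of -3.08 (SE 0.368, n = 3 arrays per group, limma over arm pairs, adjusted p = 0.0035). MiR-194, which is clustered with miR-192, fell by 1.64 (SE 0.401) while miR-194* rose by 0.98 (SE 0.292), and miR-92b fell by 1.12 (SE 0.349) while miR-92b* rose by 1.24 (SE 0.224). The differences of -2.62 and -2.36 both had an adjusted p of 0.0035, and all 3 differences passed under each scaling and without each array. With the offset the miR-195 difference shrank to -1.82. In total 24 of the 92 differences between arms passed.

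MiRNAs whose hairpins derive from Alu repeats stood on the rising side. All 10 probes of 9 such miRNAs passed as higher, with log2 fold changes from 0.87 for the miR-566 precursor to 1.92 for mature miR-566 and a median of 1.52. Among them were miR-1303 at 1.91, the miR-619 precursor at 1.82, miR-1285 at 1.72, miR-1273 at 1.64 and miR-1304 at 1.39. This list was drawn up after the rises of several members had been seen, so no test of the group was made. Without HDAC6 3, and with arrays centred on control probes, 9 of the 10 passed.

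The split of the 6 arrays by transfection gave 266 changed probes, and the highest count among the other splits was 0. As many probes were found in 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05.

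Falls outnumbered rises among miRNAs with low numbers, which tend to be the earlier described and more conserved ones, and rises outnumbered falls among those numbered 500 and above. Of 183 guide strands numbered under 500, 97 fell, 13 rose and the rest did not pass (median -0.87), whereas of 203 numbered 500 and above 17 fell and 67 rose (median 0.33), and each median kept its sign under every scaling and without each array, at -0.53 and 0.21 with the offset. Of the minority calls, the 13 rises numbered 8 without HDAC6 1 and 7 with control-probe centring, and the 17 falls numbered 7 without Mock 1 or HDAC6 3, 9 without HDAC6 1, and 8 with repeated quantile normalization, with control-probe centring or with the offset. Intensity-dependent normalization is argued against as the whole cause, since the low-numbered probes lay lower by more than 0.2 in all 5 quintiles of mean level. The difference ran from -0.40 in the dimmest to -1.96 in the brightest, with a bootstrap interval below 0 in each. The bootstrap resampled probes and not arrays, so these intervals measure the spread over probes alone. A lower share of short RNA in the HDAC6 sample stays open: the median of 0.331 of the high-numbered guide strands is part of the pattern itself, and its zero is set by the normalization, so it decides nothing, while their median lay 0.414 above the mean of 7 small RNA controls (SD over the controls 0.339), which runs against it only if these probes bind short RNA. Binding of longer RNA by high-numbered probes stays open, because the changes of mature and precursor probes numbered 500 and above had a Spearman rho of 0.256 across 29 pairs (permutation p = 0.182), between the values set for and against it and no higher than the 0.269 across 48 pairs numbered under 500 (permutation p = 0.0661), and an effect of HDAC6 on the more conserved miRNAs may also hold and was not tested.

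Mature probes lay lower relative to precursor probes of the same miRNA, with a median difference of -0.40, and medians of -0.92 in the 48 pairs numbered under 500 (21 mature lower and 2 higher) and 0.05 in the 29 numbered 500 and above (3 lower and 7 higher), classes whose difference was not tested. Intensity-dependent normalization cannot be told apart from a true difference. The guide strands lay below the precursors by more than 0.2 in 4 of 5 quintiles of mean level, the outcome set beforehand against this cause. It was not taken as decisive, because the difference was -0.01 in the second quintile (bootstrap interval -0.49 to 0.15). In the fourth quintile the interval ran from -1.87 to 0.006. The brighter 2 quintiles, at -1.02 and -1.25, held 10 and 17 precursors, and without them the differences were -0.34, -0.01 and -0.52. A lower share of short RNA in the HDAC6 sample also stays open. Star strands differed from guide strands by -0.102 in median log2 fold change, within the 0.2 set beforehand as the outcome for it. The bootstrap interval of -0.376 to 0.237 is too wide to decide. Among numbers under 500 the star strands lay 0.483 above the guide strands (0.101 to 0.769). That class was set after the values were seen, so this difference decides nothing. Both intervals resampled probes and not arrays. The guide strands included both arms of some miRNAs, so their contrast with star strands does not cleanly separate guides from passengers. Slower processing of hairpins after HDAC6 transfection may be a further explanation, which these arrays did not test.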
